A study of Arabidopsis thaliana with 4 samples.

How the data were processed

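Total RNA from rosette leaves of Arabidopsis thaliana was labelled with Cy3 and hybridised to 1-colour Agilent arrays, with 2 biological replicates of each of 2 plant lines per the labels. The control line IS-GUS-2-17 carries an estrogen-inducible silencing construct against the GUS reporter, and the line IS-tAPX-19-23 carries one against the thylakoid ascorbate peroxidase. Per the labels' protocols, plants of both lines grew for 17 days in continuous light of 100 µmol photons per square metre per second. They were then sprayed with 100 µM estrogen, and leaves were taken 2 days later. Arrays from unsprayed plants, and from other lines of either construct, are not analysed here.

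The deposited scanner tables hold spot intensity on a linear scale, made with Agilent Feature Extraction 9.1 and protocol GE1-v5_91_0806 per the file headers. That software subtracted background, removed spatial trends and replaced the smallest values by a surrogate, per the file headers. The authors' processed table holds intensity values for 24227 of the 37478 probes, equal on each array to 1 of the scanner columns (negative-control level subtracted) within a relative tolerance of 0.001 for 100% of them. Its column medians were 1246, 1193, 1393 and 1357, so it was linear and uncentred, with no scaling between arrays. It was used only as an alternative.

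The 4 arrays were on 1 slide and came from 1 scan, so no slide or scan batch could be tested. The GUS line took positions 1 and 2 of the slide and the tAPX line positions 3 and 4, so position and line cannot be told apart. Each array had 37685 spots other than controls. Of these, 63.6% to 68.5% were well above background and 0 were saturated. The spots of 23 probes printed 10 times each had a median SD of 0.068 log2 units within an array. With 2 arrays per line, their number limits the precision of every comparison.

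From the deposited intensities, the processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Control spots were left out, and so were 271 probes with a spot marked non-uniform on any array. Spots of 1 probe were averaged. Probes well above background on both arrays of at least 1 line were kept, 23897 in all, of which 20279 name a gene locus and 3618 do not. For 443 genes with several probes the brightest was taken, and for 0 of these did the probes go 2-fold in opposite directions. This left 19813 genes, of which 19693 loci were matched to the RefSeq gene table of assembly TAIR10.1, used only for symbols and for the order of genes. The array's own locus names were kept for the rest. No coordinates are given, since the files name no genome build.

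Lines were compared with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3) as tAPX line minus GUS line, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The spread came from 2 residual degrees of freedom and a prior worth 2.02. A 2-sided exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is reported. As a measure of size, genes were counted whose every array of one line was at least 2-fold above every array of the other. Values with an error are means ± SD of 2 arrays or log2 differences with limma's standard error. Where a probe was not well above background on either array of a line, the fold is given as "at least". That bound sets the bright line's mean against the dim line's mean, with each dim value raised to the lowest signal well above background on its array. It holds for the processed signal only, and another background correction can give a smaller fold.

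Before the data were examined, 24 gene lists were fixed, with 368 distinct genes of which 330 were measured, along with the tests, the alternatives and the rule for the genes named. The rule took tAPX and its stromal relative sAPX, then 12 genes higher and 12 lower, then up to 4 members of each list with the smallest p. As fewer than 12 genes passed in either direction, the 12 with the largest moderated t were taken. Genes named outside this rule are said to be chosen after their values were seen. Lists were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with the correlation estimated from the arrays. The fry test of limma was run beside it.

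The lists were the ascorbate and glutathione cycle, other antioxidant enzymes, oxidative stress response, high light and singlet oxygen, cold response, flavonoids and anthocyanins, salicylic acid defence, jasmonate response, early touch and wounding, heat shock, abscisic acid and drought, photosynthesis, chlorophyll and plastid signalling, glucosinolates, senescence, iron status, auxin response, circadian clock, small RNA silencing and reference genes. Markers of other tissues or cell types made up the lists for flowers and meristems, roots, guard cells and trichomes, and phloem.

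The steps were tested on 20 simulated sets of 19813 genes with the measured means, the spread estimated by limma and 200 changed genes. Of genes changed 16-fold, 72.5% passed the adjusted threshold, and of those changed 256-fold 93.0%, against 3.60% at 4-fold and 0.100% at 2-fold. Of genes changed 4-fold, 88.7% were at least 2-fold apart on every array. In the same sets a median of 209.5 unchanged genes, with a range from 190 to 239, also met that measure, and a median of 5 unchanged genes passed the adjusted threshold. A list of 20 genes lowered by 0.80 log2 units was found by camera, at the preset correlation, in 20 of the 20 sets. The simulated genes varied independently, so this does not show how camera calls lists of correlated genes.

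Alternatives covered the background correction (normexp with an offset of 50), quantile normalization, median centring, the authors' processed values, the filter on dim probes, non-uniform spots, the choice among probes, an intensity trend in eBayes, the replicate number as a block, each array left out in turn, the thresholds and the set test. Leaving out an array leaves a line with 1 array, which is then assumed to vary like the other line. Figures were drawn with matplotlib.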

Results

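Transcripts of rosette leaves were measured on 4 arrays, 2 of the control line IS-GUS-2-17 (the GUS line) and 2 of IS-tAPX-19-23 (the tAPX line). In both lines estrogen switches on RNA interference, against a bacterial reporter in the first and against the thylakoid ascorbate peroxidase, tAPX, in the second. tAPX removes hydrogen peroxide at the thylakoid membrane of the chloroplast. The comparison addresses how leaf gene expression responds when this scavenger is silenced for 2 days. The 75th percentile of the processed signal was 2454 and 2408 on the GUS line arrays and 2771 and 2752 on the tAPX line arrays.

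The targeted transcript tAPX (AT1G77490) was 9.22-fold lower in the tAPX line, which leaves 10.8% of the control level. Its processed signal was 19356 and 9689 on the GUS line arrays against 1611 and 1768 on the tAPX line arrays. The log2 level was 2.49 ± 0.69 in the GUS line and -0.71 ± 0.10 in the tAPX line (SD, n = 2 each). The log2 difference was -3.20 with a standard error of 0.39 and a 95% interval from -4.27 to -2.14. The transcript of sAPX (AT4G08390), the stromal ascorbate peroxidase, differed by -0.55 with a standard error of 0.51, and the arrays of the lines overlapped. Over all genes the adjusted p from limma was 0.410 for tAPX and 0.866 for sAPX. The lower level of tAPX therefore did not pass the threshold, although both its arrays lay below both control arrays. A single probe reads each of these genes. Whether the tAPX probe also reads RNA of the silencing construct was not tested, so the 10.8% is the level of this probe, not of the intact transcript alone. tAPX lay between -3.69 and -2.72 in every alternative tried.

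**Figure D1:**
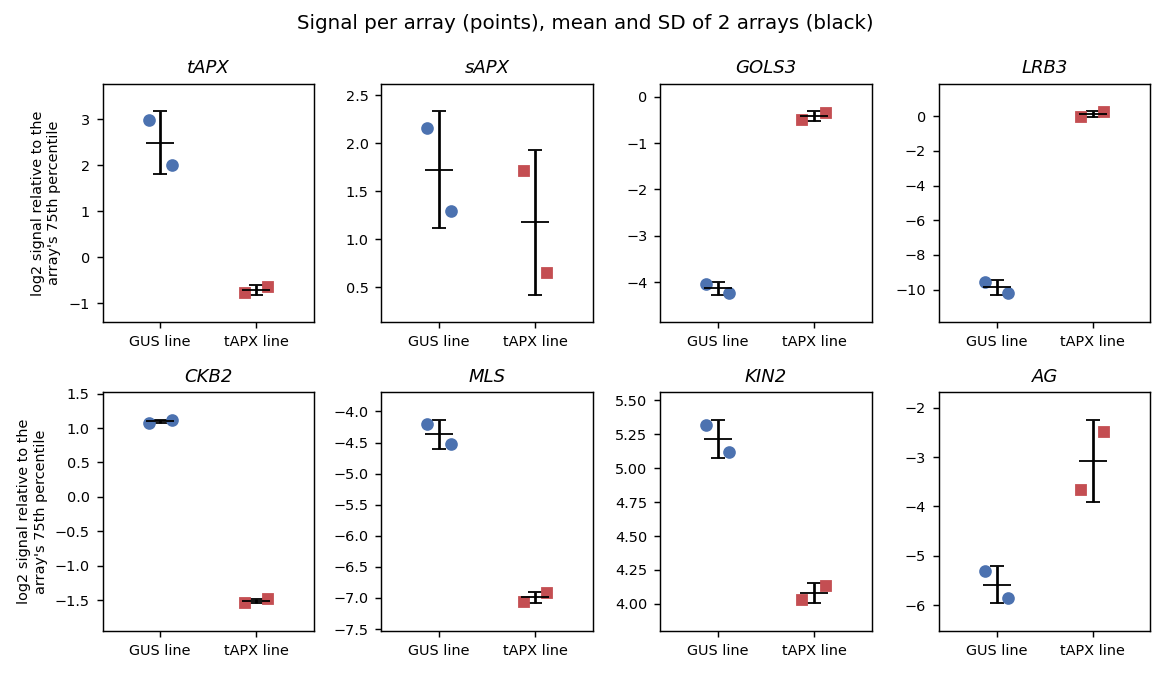
Log2 signal relative to the array's 75th percentile (vertical axes, each panel with its own range) for 8 genes in the GUS line (circles) and the tAPX line (squares), with the mean and SD of 2 arrays in black. The tAPX arrays of the target lie at -0.78 and -0.64, below the control arrays at 2.98 and 2.01, while the arrays of sAPX overlap.

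The genes with the largest moderated t among those higher in the tAPX line were mostly near or below background in the GUS line. LRB3 (AT4G01160), which encodes a BTB/POZ domain protein, was at least 202-fold higher, and MYB87 (AT4G37780), a MYB transcription factor, at least 33.8-fold higher. GOLS3 (AT1G09350), a galactinol synthase, was measured on all arrays and was 13.2-fold higher (log2 difference 3.72, standard error 0.19). AT5G59845 and AT2G39540, which the array describes as gibberellin-regulated family members, were 165-fold and at least 50.8-fold higher. The protein kinase gene AT3G07070 was at least 245-fold higher, and RR21 (AT5G07210), a response regulator of cytokinin signalling, at least 5.21-fold. Genes of undescribed function completed the group, with AT1G71470 at least 1038-fold, AT4G30230 34.0-fold, AT3G01345 7.20-fold and AT4G37860 at least 2.5-fold higher. The receptor kinase-related gene AT5G41290 was at least 3.3-fold higher. Their adjusted p ran from 0.0712 for LRB3 to 0.288, so none of these 12 passed. With normexp background correction the log2 differences of the dim genes moved by over 1.5-fold, to 7.70 for AT1G71470, 5.58 for AT3G07070, 5.44 for LRB3, 3.35 for AT2G39540, 2.73 for MYB87, 0.95 for RR21, 0.52 for AT5G41290 and 0.47 for AT4G37860. As folds, all of these lie below the bounds given above, which hold for the processed signal only. Without replicate 1 or 2 of the tAPX line the log2 difference was 12.62 and 10.72 for AT1G71470, in place of 11.67. For AT3G07070 it was 9.90 and 8.43, in place of 9.16.

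Among the genes lower in the tAPX line, AT4G16940, a disease resistance gene of the TIR-NBS-LRR class, was 34.9-fold lower. CKB2 (AT4G17640), a regulatory subunit of casein kinase, was 6.09-fold lower, with a log2 difference of -2.61 and a standard error of 0.17. MLS (AT5G03860), malate synthase of the glyoxylate cycle, was 6.17-fold lower. A pair of genes linked to flowering time were also in this group, SPL5 (AT3G15270) at 4.59-fold and BFT (AT5G62040), a relative of the flowering signal FT, at 3.14-fold lower. The receptor kinase genes AT3G21340 and AT3G53590 were at least 2.86-fold and 3.21-fold lower, and AT1G78450, of the SOUL heme-binding family, 2.98-fold. AT1G20070 was 3.91-fold lower and AT5G42610 4.40-fold, both of undescribed function. CYP96A5 (AT2G21910), a cytochrome P450, and IMPA-7 (AT3G05720), an importin alpha, were at least 1.47-fold and at least 1.05-fold lower. None of these 12 passed, with adjusted p from 0.174 to 0.410. With normexp the log2 difference moved to -3.72 for AT4G16940, -1.37 for MLS, -1.14 for AT5G42610 and -0.69 for AT3G53590. For the genes with a bound it moved to -0.95 for AT3G21340, -0.61 for CYP96A5 and -0.55 for IMPA-7. As a fold, the value of AT3G21340 lies below its bound.

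Over all 19813 genes, limma gave 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1320 genes, 595 higher and 725 lower, where chance alone gives 991. That count was 2937 without replicate 2 of the GUS line and 1411 without its replicate 1, but 519 and 634, below 991, without replicate 1 or 2 of the tAPX line. It was 2377 when the arrays were parted by replicate number and 170 for the remaining way to part them. LRB3 passed with quantile normalization (adjusted p = 0.0152) and with median centring (adjusted p = 0.0307). By size, 188 genes were at least 2-fold higher on every tAPX line array than on every GUS line array and 60 were at least 2-fold lower. For 36 of the higher and 16 of the lower genes one line was not well above background, so only a bound of the fold is known. The count of 248 was 135 with normexp background correction. In simulated arrays with the same spread a median of 209.5 unchanged genes met the measure, but these arrays were drawn independently and hold no structure that measured arrays share. When the replicate 2 arrays were set against the replicate 1 arrays instead, 524 genes met it, and the remaining way to part the arrays gave 10. The count was larger when any array was left out, as fewer arrays have to differ: it was 1352 without replicate 2 of the GUS line, 743 without its replicate 1, 562 without replicate 1 of the tAPX line and 681 without its replicate 2. On the first principal component, with 50.5% of the variance, replicate 1 of the GUS line lay at -71.5 and the other arrays between 1.4 and 45.6.

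**Figure D2:**
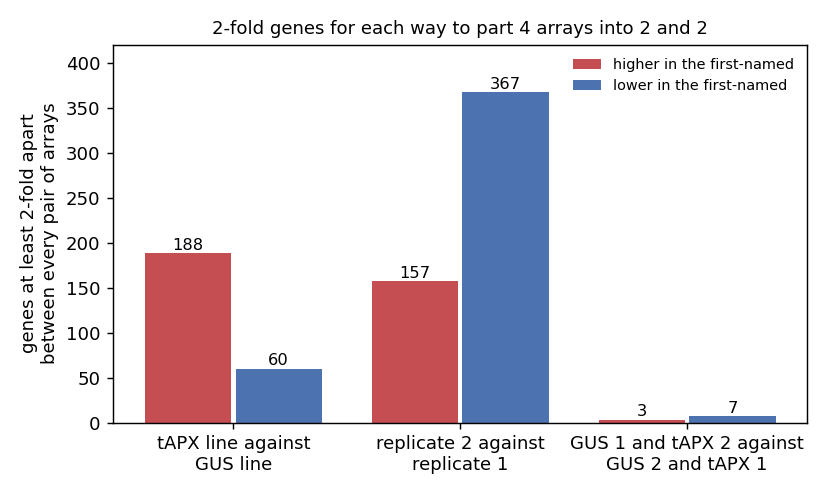
Number of genes (vertical axis) at least 2-fold apart between every array of one pair and every array of the other, for the 3 ways to part 4 arrays into pairs; bars give genes higher and lower in the pair named first. The split by line gives 188 and 60 genes, and the split by replicate number gives 157 and 367.

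No member of the 24 gene lists passed over all genes tested. Tested as groups with a preset correlation, 5 lists were lower in the tAPX line, and 0 lists passed in the other direction. With an estimated correlation each of the 5 had an adjusted p = 0.900, so no list call held there. The fry test passed 0 lists for a shift in one direction (smallest adjusted p = 0.957) and 1 list, cold response, for change in either direction. The latter test ignores the sign, and the cold member with the largest moderated t was GOLS3, which was higher. That pass therefore does not show a lower level.

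Cold-regulated transcripts were lower in the tAPX line, with a median log2 difference of -0.82 over 18 measured members and 16 of them below 0. KIN2 (AT5G15970) had a log2 difference of -1.14 with a standard error of 0.19. RD29A (AT5G52310), a dehydration and cold marker, was 2.17-fold lower, and COR28 (AT4G33980) 1.99-fold lower. The 2 exceptions were GOLS3 with its 13.2-fold higher level and ADH1, named after its values were seen, at 0.78. Of the CBF transcription factors that drive cold genes, named here after their values were seen, CBF3 differed by -0.89 and CBF2 by -1.12, while the arrays of CBF1 overlapped. On both tAPX line arrays, 11 members were below both control arrays and 2 above, where chance parts 33.3% of genes in either direction and 38.7% of all tested genes were parted. Adjusted over the list alone, GOLS3 and KIN2 passed, against 0 members over all genes. Camera gave an adjusted p = 0.000659 with the preset correlation and 0.900 with an estimated correlation. With an array left out, which leaves 1 array in a line, the adjusted p at the preset correlation ran from 2.74e-05 to 0.0234.

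Nuclear photosynthesis genes were slightly lower in the tAPX line, with 31 of 33 members below 0 and a median log2 difference of -0.20. RBCS2B (AT5G38420), a small subunit of Rubisco, was 1.66-fold lower and PETC (AT4G03280), the Rieske protein of the cytochrome complex, 1.78-fold lower. PETE2, a plastocyanin, differed by -0.48 and PSBS, the photosystem subunit of energy quenching, by -0.47. The camera adjusted p was 0.000659 with the preset correlation and 0.900 with an estimated correlation. The call was lost with quantile normalization (mean -0.10, adjusted p = 0.207) and without replicate 1 of the GUS line (mean 0.04, median 0.02). The median lay at percentile 21.9 of 10000 random lists matched on mean signal, whose central 95% ran from -0.31 to -0.01. Chlorophyll synthesis and plastid signalling genes did not pass (16 members, median -0.15, adjusted p = 0.390), except without replicate 2 of the GUS line (0.0234). In that list PORC, a protochlorophyllide reductase, differed by -0.64 with overlapping arrays and GLK1, a regulator of chloroplast genes, by -0.22.

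Early auxin-induced genes had the lowest median of all lists, -1.17 over 10 members. IAA3 was 2.25-fold lower, IAA2 1.85-fold, IAA1 2.72-fold and IAA5 3.94-fold, each an Aux/IAA repressor of the auxin response. The log2 difference was -0.53 for IAA1 and -0.61 for IAA5 without replicate 1 of the GUS line, in place of -1.45 and -1.98, and -2.36 and -3.35 without its replicate 2. Clock genes had a median of -0.52 over 13 members, of which 5 were above 0. LUX was at -1.23, TOC1 at -0.83, GRP7 at -1.09 and FKF1 at -0.84. Transcripts induced within minutes of touch or wounding had a median of -0.32 over 10 members, with the ethylene response factors ERF6 at -1.09 and ERF5 at -1.08. The preset correlation gave adjusted p = 0.0372 for the auxin and clock lists and 0.0448 for touch and wounding, and an estimated correlation gave 0.900 for each. Adjusted over the list alone, ERF6 passed, and 0 members of the auxin and clock lists did. The auxin call was lost without replicate 1 of the GUS line, with a mean of -0.14 in place of -0.91. The median was then -0.44 in place of -1.17. The auxin call was also lost without replicate 2 of the tAPX line (mean -0.40). Between replicate 2 and replicate 1 the median difference of this list was -1.75 in the GUS line and -0.88 in the tAPX line. The clock call was lost with normexp (adjusted p = 0.0558), without replicate 2 of the GUS line (0.159) and without replicate 1 of the tAPX line (0.0873). The touch call was lost with normexp (0.0602), with quantile normalization (0.0812) and without replicate 1 of the tAPX line (0.0675), and its mean turned from -0.44 to 0.04 without replicate 2 of the GUS line.

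The ascorbate and glutathione cycle and the other antioxidant enzymes did not pass as groups. In the ascorbate and glutathione cycle, the cytosolic peroxidase gene APX2 was 2.04-fold higher (log2 difference 1.03, but 0.32 with normexp) and MDAR2, a monodehydroascorbate reductase, 1.71-fold higher. DHAR3 differed by -0.57 and APX6 by -0.45. The 20 members had a median of -0.07, a mean of 0.06 and an adjusted p = 0.922, and the direction of the test turned with quantile normalization. Among the 17 other antioxidant enzymes (median -0.32, adjusted p = 0.529), the superoxide dismutase CSD1 differed by 0.71 and its copper chaperone CCS by 0.54. The catalase CAT3 differed by -0.59 and the glutathione peroxidase GPX1 by -0.69. Transcripts commonly induced by oxidants had 14 of 19 members above 0 (median 0.26, adjusted p = 0.113), with the ferritin FER1 at 1.08 and NAC013 at 0.45. The median of this list was 0.66 between the replicate 1 arrays and -0.10 between the replicate 2 arrays. It passed with non-uniform spots kept (adjusted p = 0.0294), without replicate 2 of the GUS line (0.0236) and without replicate 2 of the tAPX line (0.00213), while without replicate 1 of the tAPX line its mean was 0.06 (0.861). The 10 genes of high light and singlet oxygen had a median of 0.25 (adjusted p = 0.775), with ELIP2, an early light-induced protein, at -0.29.

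Salicylic acid defence genes had 14 of 19 members above 0 and a median of 0.31. EDS5, which exports the precursor of salicylic acid from chloroplasts, was 1.78-fold higher, PBS3 2.81-fold, CBP60G 1.93-fold and PR5 2.78-fold. The log2 difference was 0.83 for PBS3 and 0.63 for PR5 without replicate 1 of the GUS line, in place of 1.49 and 1.48, and 2.15 and 2.32 without its replicate 2. For PR5 it was 0.85 and 2.11 without replicate 1 or 2 of the tAPX line. Heat shock genes had a median of 0.34 over 19 members, with the chloroplast chaperone HSP21 5.94-fold higher (log2 difference 2.57, but 1.6 with normexp, 1.82 without replicate 1 of the tAPX line and 3.32 without its replicate 2) and HSFB1 1.75-fold higher, while HSFA7A differed by -0.82. Neither list passed (adjusted p = 0.0520 and 0.0862). Between the replicate 1 arrays the median difference was 1.05 for defence and 0.81 for heat shock, against -0.26 and -0.21 between the replicate 2 arrays. Both passed with median centring (adjusted p = 0.0382 for defence and 0.0451 for heat shock), with non-uniform spots kept (0.0156 and 0.0331) and without replicate 2 of the tAPX line (0.000292 and 8.45e-07). The defence list also passed with normexp (0.0247), with the authors' values (0.0340), with probes well above background on all arrays (0.0447), with every probe tested (0.0454) and without replicate 2 of the GUS line (6.17e-05). Without replicate 1 of the GUS line the mean of the defence list was -0.03, and without replicate 1 of the tAPX line that of heat shock was -0.14.

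The 20 flavonoid and anthocyanin genes had a median of -0.14 and did not pass as a group (adjusted p = 0.260). The MYB genes PAP2, PAP1 and MYBL2 differed by -1.91, -1.78 and -0.85, and PAL1 of general phenylpropanoid synthesis by 0.49, while PAP2 differed by -0.95 with normexp and PAP1 by -2.43 and -1.13 without replicate 1 or 2 of the GUS line. Over all genes their adjusted p ran from 0.621 to 0.764, so none of the 4 passed. Of the other regulators in the list, named after their values were seen, TTG1 differed by -0.05 and MYB111 by 0.40. The list passed without replicate 2 of the tAPX line (mean -1.04, adjusted p = 0.00130), and its mean was 0.14 without replicate 1 of that line. Jasmonate genes had a median of -0.17 over 22 members (adjusted p = 0.351), with ORA59 at -1.32 (-2.01 and -0.64 without replicate 1 or 2 of the GUS line). They passed without replicate 1 of the GUS line (mean -0.63) and without replicate 2 of the tAPX line (-0.65), and the mean was 0.26 and 0.28 without the other arrays of these lines. Among abscisic acid and drought genes (17 members, median -0.08, adjusted p = 0.589), P5CS1 of proline synthesis differed by -1.33, DREB2B by -0.54 and RD22 by -0.73. Iron status genes had a median of -0.51 over 11 members (adjusted p = 0.0918), with the ferritin FER3 at -0.72 and the transporter OPT3 at -0.69, against FER1 at 1.08 (0.47 and 1.68 without replicate 1 or 2 of the GUS line). They passed with non-uniform spots kept (adjusted p = 0.0342), without replicate 1 of the GUS line (0.0244) and without replicate 2 of the tAPX line (0.000329), while without replicate 1 of the tAPX line the mean was 0.17. Glucosinolate genes had a median of -0.08 and a mean of 0.01 over 15 members (adjusted p = 0.683), with the regulators MYB29 at 0.69 and MYB34 at -0.36. Senescence genes had a median of 0.21 over 12 members (adjusted p = 0.214), with NYC1 of chlorophyll breakdown at 0.52. The senescence list passed without replicate 2 of the GUS line (adjusted p = 0.00518), and the abscisic acid and glucosinolate lists without replicate 1 of that line (0.0236 for each).

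Genes of the RNA interference machinery had 6 of 7 members above 0 (median 0.19, adjusted p = 0.113), with AGO2 at 0.62, DCL2 at 0.54 and DCL1 at 0.36. Both lines carry silencing constructs. Of the flower and meristem markers, 5 were measured, and AGAMOUS (AG) was 5.68-fold higher (log2 difference 2.51, but 1.62 with normexp and 1.92 without replicate 2 of the tAPX line) while SEP3 was 2.33-fold lower. Adjusted over the list alone both passed, and the group did not (median 0.42, adjusted p = 0.631), except without replicate 1 of the tAPX line (0.0237). Of the root markers, 3 were measured (median -0.30, adjusted p = 0.887). PYK10 was 2.75-fold higher, passing over the list alone. NRT2.1 was at least 3.37-fold lower, but its log2 difference of -0.82 with normexp lies, as a fold, below that bound. The log2 difference of NRT2.1 was -3.03 and -0.91 without replicate 1 or 2 of the GUS line. Guard cell and trichome markers had a median of 0.10 over 9 members (adjusted p = 0.529, GL2 at 0.33) and the 3 phloem markers a median of 0.11 (adjusted p = 0.529, APL at 0.35). The 11 reference genes had a median of 0.00 (adjusted p = 0.922), with ACT2 at -0.45 and YLS8 at 0.13. Apart from cold response, touch and wounding, flowers and roots, 0 members of any list passed when adjusted over the list alone.

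**Figure D3:**
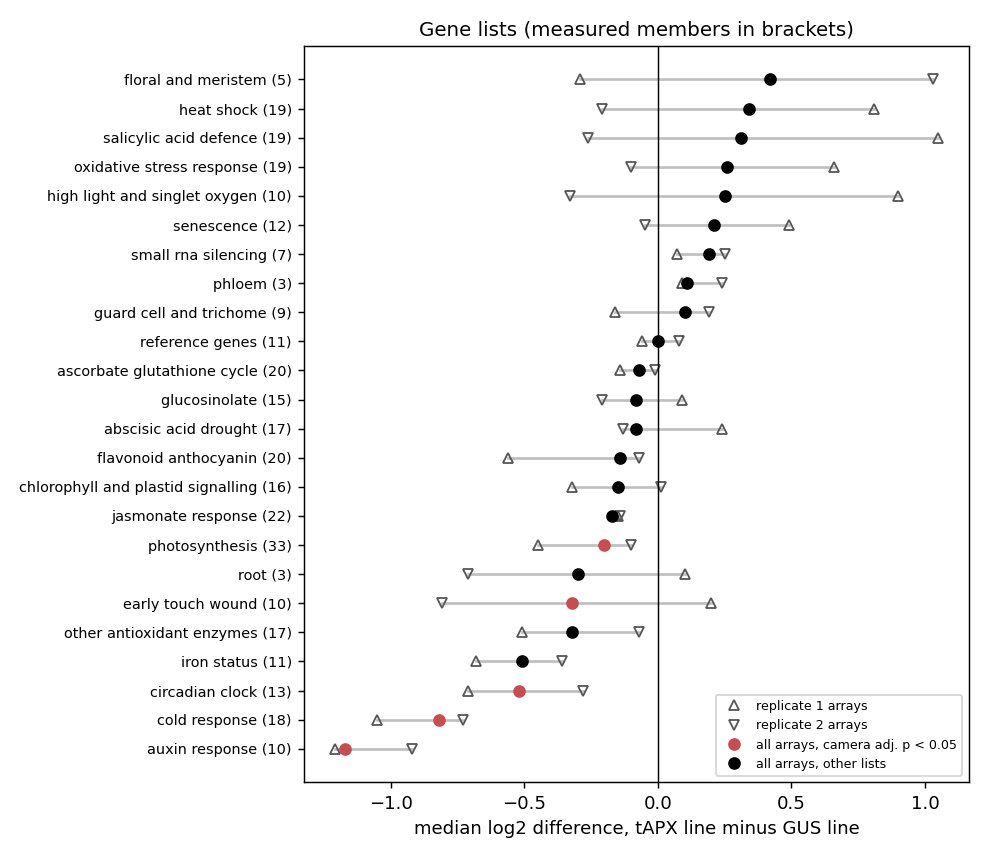
Median log2 difference between the lines (horizontal axis, tAPX line minus GUS line) for the 24 gene lists, over all arrays (filled circles) and between the replicate 1 arrays or the replicate 2 arrays (triangles up and down). The 5 lists below the camera threshold with a preset correlation lie below 0, cold response at -0.82 and auxin response at -1.17.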

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

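Probes that name no gene locus lay outside the comparison of genes and were looked at separately. Among the 3618 of them tested, 23 were at least 2-fold higher on every tAPX line array than on every GUS line array, and 23 were at least 2-fold lower. Together they were 1.27% of such probes, against 1.25% of genes, of which 188 were higher and 60 lower. With limma 0 of these probes passed at an adjusted p under 0.05, and 350 had an unadjusted p under 0.05, where chance gives 181. The difference between these probes and the genes was not tested. The groups of 2 arrays are too small for a test of single outlying arrays.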

How the results depend on the processing

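The direction of tAPX held in all 15 alternatives (from -3.69 to -2.72 log2 units, also the range with each array left out), and its adjusted p ran from 0.208 to 1. The count of genes past an adjusted p of 0.05 was 0 with each array left out and in all but these settings: 1 gene with quantile normalization, 1 with median centring and 1 at an adjusted p under 0.1. The genes at least 2-fold apart numbered 248, and 220 with values raised to the background floor, a setting chosen after seeing the data. They numbered 135 with normexp, and from 562 to 1352 with an array left out. Fewer arrays then have to differ, which raises the count by construction, and the cause of the spread among these counts was not tested. Of the lists, 5 passed in the main setting, 3 with quantile normalization, 9 with non-uniform spots kept, 0 with the estimated correlation and from 4 to 10 with an array left out. Here too the cause was not tested. Leaving out an array leaves a line with 1 array, which is assumed to vary like the other line. The slide as a block was not run, since there was 1 slide.

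The arrays share only a replicate number between the lines, and no label ties the number to a batch. Deviations from the line means correlated at 0.51 across genes, which are not independent replicates. With the replicate block, limma called 0 genes (2079 at an unadjusted p under 0.05), and 454 genes were at least 2-fold apart in both same-numbered pairs, a count chosen after seeing the data. Of the lists, 7 passed with it, against 5 without: the flavonoid (adjusted p = 0.0160), iron (0.0107) and heat shock (0.0273) lists were gained and the clock list (0.0920) was lost. The block turned the test's direction for glucosinolate genes (mean 0.01) and root markers (mean -0.27).

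Of 1680 values for 113 named genes, 1661 kept their direction. The fold moved by over 1.5 times in 44 values with an array left out and in 24 others, 20 of them with normexp. AP3 turned with normexp (-0.03). With an array left out, these genes turned direction over the ranges given, in log2 units: AOC2 -1.30 to 0.24, AP3 -0.08 to 0.91, CHLD -0.86 to 0.15, JMT -0.92 to 0.01, KAT1 -0.08 to 0.49, NYE1 -0.01 to 1.54, PI -0.03 to 1.14, SEOR1 -0.42 to 0.64, SGS3 -0.07 to 0.44, SUC2 -0.01 to 0.09, TCH2 -0.69 to 0.05, TCH3 -0.57 to 0.02, TGG1 -0.05 to 0.41, TIP41 -0.04 to 0.16, UBC21 -0.03 to 0.38 and WRKY53 -0.17 to 1.13.

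List tests gave 16 lost calls and 28 gained over 384 values. The test's direction turned for the ascorbate cycle with quantile normalization (mean 0.11) and non-uniform spots kept (0.07), for guard cells with no background filter (-0.14), for reference genes with normexp (-0.02) and quantile normalization (0.06), and for roots with probes well above background on all arrays (0.58). With an array left out it turned over these ranges of the mean: abscisic acid -0.39 to 0.16, ascorbate cycle 0.00 to 0.12, chlorophyll -0.59 to 0.26, touch and wounding -0.92 to 0.04, flavonoids -1.04 to 0.14, flowers -0.29 to 0.99, glucosinolates -0.29 to 0.31, heat shock -0.14 to 0.89, high light -0.15 to 0.43, iron -0.95 to 0.17, jasmonate -0.65 to 0.28, other antioxidants -0.28 to 0.01, reference genes -0.06 to 0.02, roots -0.85 to 0.31, salicylic acid -0.03 to 0.83 and senescence -0.16 to 0.67. Signals not well above background limit the folds given as bounds.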

Other observations

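All tests in this part were chosen after the comparison of the lines had been seen, and the tests on the NDH genes and on 1 transgene site in each line also after the values they concern had been seen. Genes for the NDH complex, which carries electrons from ferredoxin back to the plastoquinone pool in chloroplasts, had a median log2 difference of -1.05 between the lines. By limma 0 of the members passed over all genes, and camera with an estimated correlation gave an unadjusted p = 0.0891 for the list, so neither test passed. For the cold response and clock lists, given above with adjusted p only, that camera test had an unadjusted p of 0.108 and 0.175. The p of the NDH list therefore cannot be set beside those adjusted values. Of 16 genes for subunits of the complex or factors linked to it, 14 were measured, all with a mean difference below 0. Of the 14, 10 had not been used to notice the pattern. Of these 10, 9 had both tAPX line arrays below both control arrays, where chance parts 33.3% of genes in either direction and 38.7% of all tested genes were parted. Among all 14, the largest log2 differences were -1.54 for NDHN (standard error 0.26), -1.50 for PNSL3 (0.32), -1.42 for CRR7 (0.20) and -1.38 for PNSL2 (0.26). The smallest were -0.13 for NDHL (0.25) and -0.65 for PNSB1 (0.22). The median was between -1.06 and -0.99 under the other scalings and between -1.21 and -0.82 with an array left out.

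The flowering signal FT differed by -1.35 (standard error 0.18), beside SPL5 at -2.20, BFT at -1.65 and SEP3 at -1.22. The 6 other measured genes of the floral transition had a median of 0.16, with SOC1 at 0.25, SVP at 0.09 and TSF at -0.85. The split by replicate number gave 524 genes at least 2-fold apart against 248 by line, which points to a structure of the arrays by replicate number, and anthocyanin genes were among them. DFR was higher in replicate 2 by 4.45 log2 units in the GUS line and 4.35 in the tAPX line. TT19 was higher by 3.91 and 4.30, and LDOX by 4.07 and 3.79. Between the lines TT19 differed by -1.58 with a standard error of 2.06, and its arrays overlapped.

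Technical explanations were weighed for the NDH genes on the 10 measured members that had not been used to notice the pattern. A shift of all probes of this brightness would leave them within random lists. Their median of -0.89 lay below the central 95% of 10000 lists of equal brightness, which ran from -0.26 to 0.25. Those lists hold unrelated genes, while the measured NDH genes had an estimated correlation of 0.434 between genes. The range therefore does not show how far correlated genes vary together over 2 arrays per line. Replicate 1 of the GUS line alone was not the source, since without it their median was -0.68. A hypothesis left open is that NDH genes may respond to the silencing of tAPX. Position on the slide and differences between the lines other than tAPX follow the lines and cannot be told apart from it.

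The lower photosynthesis list stands differently. Its median of -0.20 lay within the range of random lists of equal brightness, from -0.31 to -0.01, and without replicate 1 of the GUS line it was 0.02. Both values are what a shift of bright probes, or that array alone, would give. The random lists were drawn from all genes of that brightness, the list's own members included. Their range therefore does not part a shift of bright probes from a shift of bright photosynthesis genes. The lower photosynthesis genes may therefore come from the brightness of their probes and from 1 array, and a response to the silencing of tAPX stays open as well.

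Some genes at least 2-fold apart between the lines lay close together on the chromosomes. There were 31 same-direction pairs within 5 tested genes of each other, against a median of 10 and at most 23 in 10000 random sets. These pairs held 34 of the 188 higher and 11 of the 60 lower genes. Neighbours also shared direction in the split by replicate number. Its sets, thinned at random to equal size, had a median of 19 pairs and up to 36, but reached 31 in only 0.9% of 1000 draws. Only that split was used, and random thinning parts neighbours. How much neighbours that share expression account for therefore stays open. Tandem copies that share a probe signal stay open only in part: without pairs of the same described family 20 pairs were left, a number that 0.27% of random sets reached (median 9, highest 23), but copies described differently escape that count. The pairs formed 20 clusters over 5 chromosomes, and without the 2 densest 22 pairs were left. Random sets treated the same way had at most 19, and 0.2% of the sets from the replicate split reached 22 (median 13, highest 23). So 1 transgene site in each line is not enough by itself. The pairs left include some of the same described family. Dense sites and such tandem copies were not left out together, so the 2 explanations combined stay open. For the densest cluster alone, of GOLS3, UMAMIT25 and AT1G09400 (higher by 3.72, 3.91 and 1.93 log2 units) and AT1G09360 (at least 2.06-fold), the position of a transgene is a candidate explanation that cannot be told apart from the silencing, since the insertion sites are not known here; it holds 4 of 10 neighbouring genes, where 1000 random sets reached at most 4, and NIMIN-3 just beyond it differed by 1.46, but AT1G09390 (-0.29) breaks the run and CRB (-0.77) borders it.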
